A study of Mus musculus with 33 samples.

How the data were processed

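RNA from mouse mammary tumours was sequenced for 33 samples. Per the labels' protocols, tumours had been transplanted into mice that then received vehicle or the PKMYT1 inhibitor RP-6306, total RNA was extracted with Trizol, and libraries were made and sequenced by a commercial provider. The treatment protocol gives the dose of RP-6306 as 20 mg/kg per day for different periods, whereas the treatment field of the samples gives 20 mg/kg with a twice-daily abbreviation. The period of each sample is not given in the sources used here, and neither is the kit, its strandedness or the annotation release. Per the submitters' processing notes, the tools were STAR 2.7.10a, HTSeq and edgeR and the genome build was GRCm38.

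The deposited table of read counts held whole numbers for 54532 rows, each with an Ensembl gene identifier, and 33 columns, 1 per sample, with no other columns of samples. Of these rows, 791 had no symbol and together held 0.0482% of the counts. They were kept under their identifiers. A second deposited table held log2 CPM values. Against log2 CPM recomputed from the counts with TMM factors and a prior count of 2, these values differed by a median of 0.058 and by at most 0.058. All results were computed from the counts. CPM values in the text were computed from the counts with TMM factors over all 33 libraries.

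Samples were grouped by their titles and treatment fields. Titles ending in _7 gave 3 vehicle and 4 RP-6306 tumours. Titles without that suffix gave 4 vehicle and 11 RP-6306 tumours. The labels do not say what the suffix stands for. Titles with SPON and WT gave 5 and 5 untreated tumours, and the labels do not say which of these is the cyclin E transgenic or the PyMT tumour that the design text names. For 1 sample the title says vehicle and the treatment field says RP-6306. It was left without a group and entered no comparison. Replicates were numbered in accession order within each group, so the numbers pair nothing. The labels do not say that samples of a group came from separate animals, so p-values measure the spread between these samples. All 90 pairs of libraries within groups differed by more than sampling noise (smallest chi-square per degree of freedom 16.12, over genes with at least 10 counts in a pair), and each library counted as 1 sample.

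The 4 comparisons were RP-6306 against vehicle within each set, SPON against WT, and the difference between the 2 sets in the log2 fold change of RP-6306 against vehicle. Each was fitted with edgeR 4.0.16 in R 4.3.3 (filterByExpr, TMM, glmQLFit and glmQLFTest) on its own groups, and genes with a Benjamini-Hochberg adjusted p under 0.05 were counted as changed. The standard error of a log2 fold change was taken from the F statistic. Gene lists were tested with camera in limma 3.58.1 on voom values with a preset inter-gene correlation of 0.01, adjusted over the lists. There were 45 lists (cell cycle, stress, signalling, metabolism and cell type markers) with 1034 entries, of which 1030 matched a symbol. Lists with fewer than 3 tested members were not tested. Where a group had no count for a gene in a comparison of 2 groups, the fold was bounded with a floor of 3 counts over the group, which covers counting error only. Differences between sets are fitted values, and a bound was computed only where 1 of the 4 groups had no count and the others had more than 3, and is given only where this held without any 1 library. Where a group had 1 to 3 counts, the ratio of summed counts was given with an exact 95% interval for counting error. Folds of named genes that moved by over 1.5 times without 1 library are given beside the value.

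Designs, alternatives, lists and the rule for named genes were fixed before the data were examined. The rule took Pkmyt1, Wee1, Cdk1, Ccnb1, Ccne1, Ccne2, Cdkn1a and Mki67 in every comparison. It added the 8 largest and 8 smallest log2 fold changes among changed genes with an average log2 CPM of at least 1 and a symbol that is not a predicted gene, clone or pseudogene name. It also added, for up to 6 called lists with the smallest p, the 3 members with the smallest edgeR p. Further called lists are given by counts or by median log2 fold change. For the difference between sets no list members were added, and only the number of called lists is given. A gene that the rule named is not reported here. Epcam, Vim and Trp53 were added after their values had been seen. Gene positions came from GENCODE M21 on GRCm38.

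The alternatives were DESeq2 size factors, no filter on low counts, DESeq2 1.42.0, limma voom without and with sample quality weights, a fold of at least 2, 1 fit over the 32 grouped libraries and each library left out in turn. For the lists they were an estimated correlation and the fry test, with the same scaling, filter, weights and left-out libraries. Tests without libraries that stood apart were chosen after the data had been seen.

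The fits were tested on simulated counts with the real means, dispersions and library sizes, in which 200 genes were changed. At a fold of 2 the edgeR fit recovered 52% of changed genes in the comparison of the set titled _7 (16375 genes), 62.6% in the set without the suffix (15754 genes), 2.04% in SPON against WT (15324 genes) and 27.6% for the difference between sets (16695 genes). At a fold of 4 it recovered 86.5%, 88%, 54.6% and 62.2% for the same comparisons in that order. Each library held between 13701115 and 34637096 counts.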

Results

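RNA-seq counts were obtained from 33 mouse mammary tumour samples. In 1 set, whose titles end in _7, 3 tumours had received vehicle and 4 had received RP-6306, an inhibitor of PKMYT1, the kinase that places an inhibitory phosphate on CDK1. In the other treated set, without this suffix, 4 tumours had received vehicle and 11 had received RP-6306. A further 5 tumours titled SPON and 5 titled WT were untreated, and 1 sample with contradicting labels was kept out of every comparison. Libraries of the set titled _7 held 26517748 to 34637096 counts, and the libraries of the other groups held 13701115 to 20105407.

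Across 13074 expressed genes, the 1st principal component held 52.5% of the variance. The 7 libraries of the set titled _7 lay between -129.63 and -111.86 on it, and the 4 vehicle libraries without the suffix lay between -90.96 and -50.54. All 11 RP-6306 libraries without the suffix lay between 24.70 and 62.82, on the side of the SPON and WT tumours. Vehicle libraries without the suffix had a mean correlation across genes of 0.90 with vehicle and 0.89 with RP-6306 libraries of the set titled _7, and of 0.77 with the RP-6306 libraries of their own set. The RP-6306 libraries without the suffix had a mean correlation of 0.84 with SPON and 0.80 with WT libraries. By SPON library it was 0.88 and 0.91 for replicates 1 and 4, and 0.81, 0.80 and 0.79 for replicates 2, 3 and 5. Genes are not independent replicates, so these correlations describe the libraries and test nothing.

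**Figure D1:**
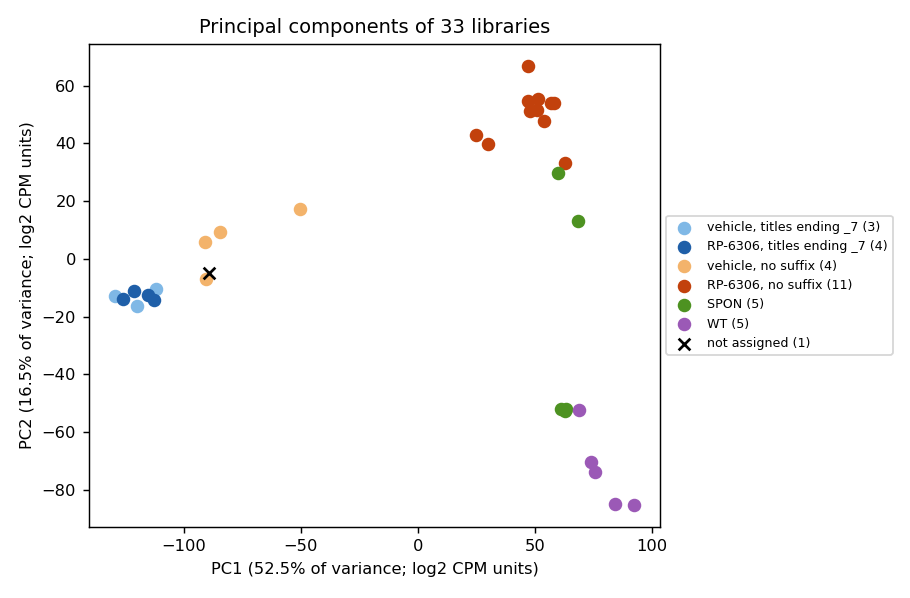
Scores of the 33 libraries on the first principal components of log2 CPM, with PC1 (52.5% of the variance) on the horizontal axis and PC2 (16.5%) on the vertical axis, each point a library coloured by group. Vehicle libraries without the suffix lie between -90.96 and -50.54 on PC1, and the RP-6306 libraries of the same set between 24.70 and 62.82.

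Whether RP-6306 changed gene expression was asked first in the set titled _7. No gene passed the edgeR test among 16699 tested. Pkmyt1 stood at 27.1 ± 4.73 CPM (SD, n = 4) under RP-6306 and 24.6 ± 8.68 CPM (SD, n = 3) under vehicle, a log2 fold change of 0.14 ± 0.23 (SE; edgeR adjusted p = 0.939). Cdk1, the kinase that drives entry into mitosis, had a log2 fold change of 0.15 ± 0.19, and Ccnb1, which encodes its cyclin partner, of 0.19 ± 0.20. Values for Wee1 (-0.02 ± 0.16), which encodes another inhibitory kinase of CDK1, and for the cyclin E genes Ccne1 (0.11 ± 0.25) and Ccne2 (-0.17 ± 0.21) also lay within 1 SE of 0. The CDK inhibitor gene Cdkn1a had -0.12 ± 0.14 and the proliferation marker Mki67 0.03 ± 0.17. At an unadjusted p under 0.05 there were 1033 genes, against 835 by chance, and the smallest adjusted p was 0.113. DESeq2 called 60 genes, edgeR without a filter on low counts called 6, and limma voom called 0. DESeq2 called Pfkfb3 (adjusted p = 0.00426), Eno2 (0.00397) and Pdk1 (0.0329), genes of hypoxia and glycolysis that edgeR did not call.

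Among the gene lists of the set titled _7, camera with a preset correlation placed hypoxia and glycolysis genes lower and interferon, T cell and NK cell genes higher under RP-6306 than other genes. Each of these calls was lost with an estimated correlation (adjusted p = 0.935 with an estimated correlation), and no member passed over all genes. The hypoxia list had a median log2 fold change of -0.75 over 25 members, 18 of which passed as lower when adjusted over the list alone. Its leading members were Pfkfb3 (-0.99 ± 0.21), Egln3 (-1.43 ± 0.33) and Pdk1 (-0.88 ± 0.23), and the overlapping glycolysis list (median -0.39, 9 of 19 adjusted over the list alone) was led by Eno2 (-1.12 ± 0.25), Slc16a3 (-0.55 ± 0.15) and Aldoc (-0.90 ± 0.25). Interferon-stimulated genes had a median of 0.48 over 42 members, 0 of which passed adjusted over the list alone, with Mx1 (0.75 ± 0.23), Oasl1 (0.73 ± 0.24) and Rsad2 (0.64 ± 0.21) leading. T cell markers had a median of 0.98 over 22 members, with Icos (1.19 ± 0.41), Thy1 (0.66 ± 0.25) and Cd4 (0.97 ± 0.38), and cytotoxic and NK cell markers one of 0.72 over 15 members, with Klrk1 (0.87 ± 0.38), Klrd1 (1.06 ± 0.47) and Ccl5 (0.44 ± 0.22). Cd4 reached 14.6 CPM in RP-6306 replicate 2, against at most 6.15 in the rest of that group. Ribosome biogenesis genes had a median of 0.14 over 30 members, led by Bysl (0.28 ± 0.12), Nop58 (0.26 ± 0.13) and Bop1 (0.21 ± 0.11), and this call was lost without vehicle replicate 2 (adjusted p = 0.469).

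With the preset correlation, camera called 15 of 45 lists in this set, 12 up and 3 down. The other called lists, by median log2 fold change, were oxidative phosphorylation (0.10), endothelium (0.25), macrophages (-0.22), B cells and plasma cells (1.97), ribosomal proteins (0.14), pericytes (0.20), G2/M and mitosis (0.11), adipocytes (1.67) and MHC class I (0.10), and each of these calls was lost as well (adjusted p = 0.935 with an estimated correlation for each). The fry test called 0 lists (smallest adjusted p = 0.964). Without RP-6306 replicate 2 the count was 9, with B cells (adjusted p = 0.258), G2/M (0.32, and 0.689 without RP-6306 replicate 3, and turned down without vehicle replicate 2, 0.469), adipocytes (0.229, and also lost without RP-6306 replicate 4 or vehicle replicate 2 or 3, up to 0.541), MHC class I (0.448, and also without RP-6306 replicate 3 or vehicle replicate 2, up to 0.914) and oxidative phosphorylation (0.538, and 0.419 without vehicle replicate 2) among those lost. Endothelium (0.272) and macrophages (0.0648) were lost without vehicle replicate 1, pericytes without RP-6306 replicate 1 (0.183), and ribosomal proteins without vehicle replicate 2 (0.395) and without RP-6306 replicate 2 (0.972), where they turned down.

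The same comparison in the set without the suffix gave 9531 changed genes of 16021 tested (59.5%), 4883 higher and 4648 lower under RP-6306. Because the labels give no tumour line, this comparison cannot tell an effect of RP-6306 from a difference between tumours. For this set, rose and fell mean higher and lower in RP-6306 than in vehicle tumours. Pkmyt1 (ENSMUSG00000023908, chromosome 17, 23726336 to 23736735 on GRCm38) stood at 78.9 ± 9.96 CPM (SD, n = 11) against 23 ± 5.1 CPM (SD, n = 4) under vehicle, a log2 fold change of 1.78 ± 0.14 (SE; edgeR adjusted p = 3.44e-08). Cdk1 (chromosome 10, 69335146 to 69352938) rose by 1.41 ± 0.26, Ccnb1 (chromosome 13, 100778650 to 100786570) by 1.57 ± 0.27, Mki67 (chromosome 7, 135689784 to 135716361) by 1.52 ± 0.19 and Wee1 (chromosome 7, 110122046 to 110143286) by 0.60 ± 0.16. Ccne1 (chromosome 7, 38097984 to 38107534) fell by 1.30 on the log2 scale, with an SE of 0.23, and Ccne2 (chromosome 4, 11191351 to 11204779) fell by 0.72 with an SE of 0.23. The call of Ccne2 was lost without vehicle replicate 4 (log2 fold change -0.47, adjusted p = 0.122). Cdkn1a (chromosome 17, 29090976 to 29100727) had a log2 fold change of -0.17 ± 0.25 (adjusted p = 0.571). At a fold of at least 2, 4744 genes changed, 2122 higher and 2622 lower. Slightly more genes were also lower than higher with DESeq2 size factors (4809 and 4670), without a filter on low counts (5278 and 4924), with DESeq2 (5331 and 4974), with limma voom (4782 and 4678) and in 1 fit over the 32 libraries (4168 and 3958).

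Genes of luminal epithelial cells were higher and genes of mesenchymal cells lower in the RP-6306 tumours of this set, by member counts and by camera with a preset correlation (adjusted p = 0.501 with an estimated correlation for each of the 3 lists). Of 27 luminal epithelium genes, 24 rose and 1 fell (median 3.65; 24 and 1 when adjusted over the list alone), among them Erbb2 (1.86 ± 0.19), Gata3 (1.69 ± 0.19) and Prlr (3.89 ± 0.44), which encode a growth factor receptor, a luminal transcription factor and the prolactin receptor. Without vehicle replicate 1 the value of Prlr was 4.71. Of 23 basal and myoepithelial genes, 10 rose and 7 fell (median 0.80; 10 and 7 adjusted over the list alone), and camera did not call this list (adjusted p = 0.397). Of 25 EMT and claudin-low genes, 23 fell and 0 rose (median -2.27; 23 adjusted over the list alone), led by Prrx1 (-3.56 ± 0.20), Tgfbi (-2.22 ± 0.15) and Itga5 (-3.57 ± 0.26). Fibroblast and collagen genes fell in 23 of 25 (median -2.70; 24 adjusted over the list alone), including Pdpn (-5.65 ± 0.34), Col6a3 (-2.84 ± 0.21) and Fbn1 (-3.12 ± 0.25). Epcam, an epithelial adhesion gene chosen after its values were seen, stood at 1430 ± 349 CPM (SD, n = 11) under RP-6306. Under vehicle it stood at 239, 26.3, 8.92 and 9.86 CPM in replicates 1 to 4, and its mean was 5.01 ± 4.43 CPM (SD, n = 3) and 3.99 ± 1.67 CPM (SD, n = 4) in vehicle and RP-6306 tumours titled _7. Vim, a mesenchymal filament gene chosen in the same way, stood at 811 ± 310 CPM (SD, n = 11) against 4910 ± 627 CPM (SD, n = 4), and at 4460 ± 168 CPM (SD, n = 3) in vehicle tumours titled _7.

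Most genes of the cell cycle and interferon lists were also higher in these RP-6306 tumours, beside the difference in luminal genes and in library correlation given above (adjusted p = 0.501 with an estimated correlation for the G1/S and interferon lists and 0.558 for G2/M). Of 37 G1/S and DNA replication genes 33 rose and 1 fell (median 0.88; 33 and 1 adjusted over the list alone), with Rfc4 (1.80 ± 0.15) and Mcm7 (1.54 ± 0.16) among them. Of 34 G2/M genes 31 rose (median 1.03; 33 rose and 1 fell adjusted over the list alone), led by Birc5 (1.63 ± 0.17), Kif11 (1.62 ± 0.18) and Bub1 (1.61 ± 0.18). Interferon-stimulated genes rose in 38 of 42 and fell in 1 (median 1.43; 40 and 1 adjusted over the list alone), with Mx2 (2.39 ± 0.18), Rtp4 (2.48 ± 0.19) and Gbp3 (1.92 ± 0.15) leading. Endothelial genes fell in 20 of 20 (median -1.19), macrophage genes fell in 19 of 24 and rose in 2 (median -1.29), and hypoxia genes fell in 17 of 25 (median -0.73), with an adjusted p = 0.501 with an estimated correlation for each of these lists.

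The 8 largest increases included Krt6b, a keratin of stratified epithelium, with 0 counts in the 4 vehicle libraries and at least 63-fold higher under RP-6306 (3.28 ± 1.32 CPM, SD, n = 11). Sox14, Pax3 and Hapln2 likewise had 0 vehicle counts and were at least 60.7-fold, 57.8-fold and 50.1-fold higher, and limma voom did not call Pax3 (adjusted p = 0.0542). Reads of Krt6b may be shared with its close relative Krt6a. Pigr, with 2 vehicle counts, was 173-fold higher by summed counts (95% counting interval 47.9 to 1430) and Ptprt, with 1 vehicle count, 151-fold (26.9 to 5960). Alox12e (6.85 ± 0.70) and Adamdec1 (6.65 ± 1.04) completed the group. The largest decreases included Acta1 (-9.62 ± 0.85), which encodes skeletal muscle actin, the cartilage proteoglycan gene Acan (-9.10 ± 0.68) and Bmp5 (-9.09 ± 0.44). Gdf10 (-8.95 ± 0.56), Grem1 (-8.60 ± 0.52), which encodes a BMP antagonist, and Stmn2 (-7.93 ± 0.66) followed. Kcna4 and Lypd6, each with 3 counts over the RP-6306 libraries, were 905-fold (309 to 4400) and 634-fold (216 to 3080) higher under vehicle by summed counts. Without vehicle replicate 1, Alox12e stood at 8.52, Adamdec1 had 1 vehicle count and was 324-fold higher by summed counts (58.1 to 12800), and Ptprt had 0 vehicle counts and was at least 36.4-fold higher. Without vehicle replicate 3, Pigr was 260-fold higher (46.5 to 10300). The bounds of Pax3 and Hapln2 were 36.3-fold without RP-6306 replicate 11 and 33.2-fold without RP-6306 replicate 1. Acta1 stood at -9.0 without vehicle replicate 2 and -11.63 without RP-6306 replicate 9, and Bmp5, with 2 RP-6306 counts left without RP-6306 replicate 7, was 1350-fold higher under vehicle by summed counts (373 to 11200). Without RP-6306 replicate 8, Acan stood at -9.92 and Stmn2 at -8.57, and Kcna4 was 2490-fold higher under vehicle (446 to 98400).

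Camera called 19 of 45 lists in this set, 12 up and 7 down. The further called lists rose for DNA repair and checkpoint (19 of 29, and 2 fell), milk and alveolar genes (10 of 14, and 1 fell), oxidative phosphorylation (24 of 46, and 3 fell), CDK1 and its regulators (12 of 16, and 2 fell), ribosomal proteins (18 of 40, and 2 fell), squamous differentiation (8 of 12, and 1 fell), MHC class I (13 of 21, and 1 fell) and ribosome biogenesis (12 of 30, and 1 fell). They fell for senescence secretory genes (18 of 27, and 6 rose) and dendritic cells (10 of 15, and 3 rose). None of the 19 held with an estimated correlation (adjusted p = 0.501 to 0.707), and all 19 were among the 32 lists that fry called. MHC class I was lost without RP-6306 replicate 7 (adjusted p = 0.0516), and ribosome biogenesis without vehicle replicate 3 (0.0581) or RP-6306 replicate 2 (0.0604) or 9 (0.0627).

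**Figure D2:**
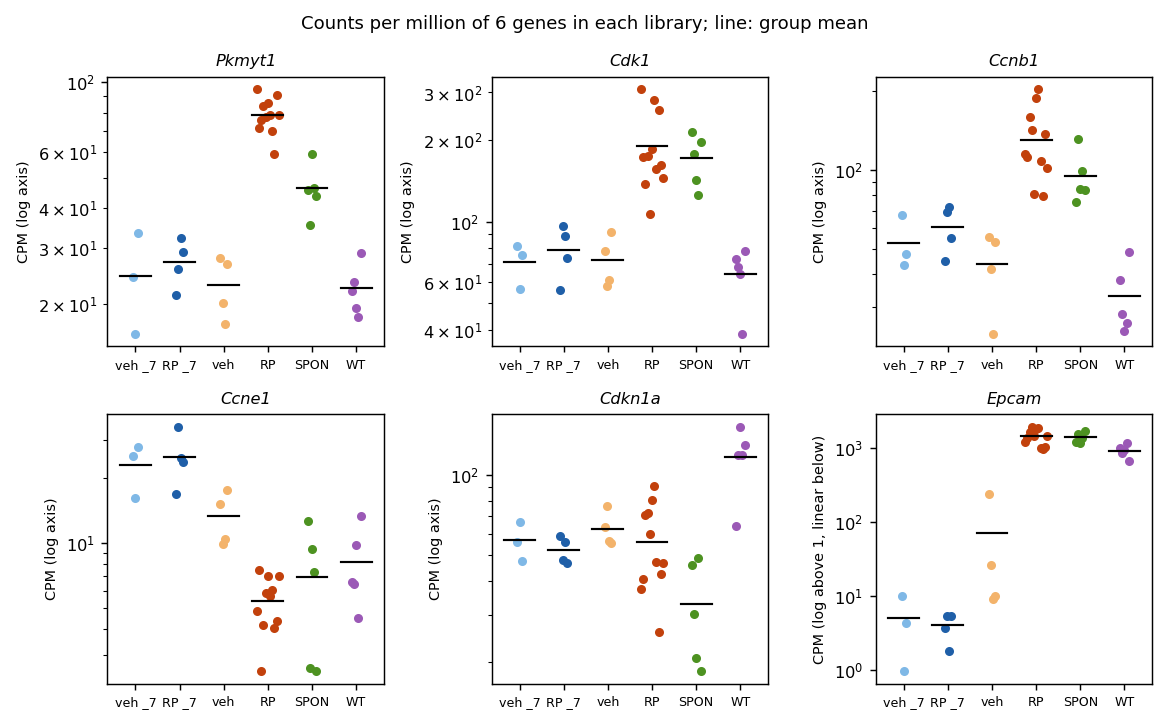
CPM of Pkmyt1, Cdk1, Ccnb1, Ccne1, Cdkn1a and Epcam on log axes (Epcam linear below 1) in each library, by group, with points for libraries and lines for group means; veh and RP are vehicle and RP-6306, with _7 for the set so titled. Pkmyt1 has a mean of 78.9 CPM in RP-6306 tumours without the suffix and 23 CPM in their vehicle tumours, against 27.1 and 24.6 CPM in the set titled _7.

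Whether RP-6306 and vehicle tumours differed alike in both sets was tested directly, as the difference of the log2 fold changes of the sets. The log2 fold changes differed for 6151 of 17095 genes (2914 higher and 3237 lower in the set without the suffix). The labels give no tumour line for any sample, so this contrast cannot tell an effect of RP-6306 from a difference between tumours. Pkmyt1 differed by 1.65 ± 0.26 (edgeR adjusted p = 5.31e-05), Cdk1 by 1.26 ± 0.37, Ccnb1 by 1.39 ± 0.39, Mki67 by 1.5 ± 0.28 and Ccne1 by -1.41 ± 0.38. Wee1 differed by 0.63 ± 0.24 (adjusted p = 0.0459), a call that was lost without any 1 of 16 of the 22 libraries (adjusted p = 0.0506 to 0.122). For Ccne2 (-0.54 ± 0.36) and Cdkn1a (-0.04 ± 0.37) no difference passed. The largest differences included the basal keratin gene Krt15 (11.83 ± 1.99), Alox15 (10.67 ± 1.91) and Alox12e (9.44 ± 2.04) upward and Otop1 (-12.83 ± 2.66), Bmp5 (-11.01 ± 2.29) and Acta1 (-10.04 ± 2.46) downward. These sizes, and those given without 1 library, are fitted and depend on the prior count, and they bound nothing, because Krt15 and Alox15 had 0 counts in the RP-6306 libraries titled _7 and Otop1 and Bmp5 in the vehicle libraries titled _7. Against a floor of 3 counts over that group, which covers counting error only, the difference was at least 9.92 for Krt15, but 53 of its 57 counts in vehicle libraries titled _7 lay in replicate 1, and without that library it was at least 6.46. Without vehicle replicate 1 of the other set it was at least 10.75. No bound is given for Alox15 and Otop1, where it would rest on 1 library, or for Bmp5 and Alox12e, which had 2 and 3 counts in the RP-6306 libraries titled _7. In the set titled _7, the calls of Alox15 (8.25, adjusted p = 0.0517) and Alox12e (7.74, 0.122) were lost without vehicle replicate 1, Otop1 (-7.85, 1) and Bmp5 (-9.17, 1) without RP-6306 replicate 4, and Acta1 (-4.43, 0.13) without RP-6306 replicate 3. Krt15 stood at 8.54 without vehicle replicate 1 of that set, Alox12e at 11.72 without its RP-6306 replicate 1 and Acta1 at -15.80 without its vehicle replicate 2. In the other set, Krt15 stood at 12.68, Alox15 at 12.41 and Alox12e at 11.10 without vehicle replicate 1. Acta1 stood at -9.40 without vehicle replicate 2 and -12.05 without RP-6306 replicate 9 of that set, Otop1 at -10.61 without vehicle replicate 4 and -13.89 without RP-6306 replicate 10, and Bmp5 at -11.68 without RP-6306 replicate 7. Camera called 16 of 45 lists, 7 up and 9 down, and 0 with an estimated correlation (smallest adjusted p = 0.634), and fry called 21, 14 of them among the 16.

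The untreated tumours titled SPON and WT were compared last. Of 15558 genes, 1303 differed, 703 higher and 600 lower in SPON, whereas limma voom had 557 higher and 766 lower. Pkmyt1 was higher in SPON, at 46.2 ± 8.63 CPM (SD, n = 5) against 22.4 ± 4.25 CPM (SD, n = 5), a log2 fold change of 1.05 ± 0.22 (SE; edgeR adjusted p = 0.0167). Cdk1 (1.42 ± 0.24) and Ccnb1 (1.52 ± 0.25) were higher and Cdkn1a (-1.81 ± 0.34) was lower. No difference passed for Wee1 (0.61 ± 0.29), Ccne1 (-0.23 ± 0.51), Ccne2 (0.44 ± 0.37) or Mki67 (0.87 ± 0.29, adjusted p = 0.0812), although DESeq2 called Mki67 (adjusted p = 0.0358). The Pkmyt1 call was lost without WT replicate 1 (adjusted p = 0.0504), 3 (0.0565) or 4 (0.0543). SPON replicates 1 and 5 held 20% and 23.6% of their counts in mitochondrially encoded genes, against 2.73% to 7.75% in the WT libraries. On the 2nd principal component, SPON replicates 1 and 4 lay at 13.01 and 29.81 and SPON replicates 2, 3 and 5 between -52.74 and -51.89, and SPON libraries had a mean correlation of 0.83 with each other and of 0.83 with WT libraries.

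Camera with a preset correlation placed cell cycle lists higher and interferon and milk lists lower in SPON than other genes, with 14 of 41 interferon genes and 7 of 17 milk genes passing as lower. With an estimated correlation none of these lists was called (adjusted p = 0.15 for G1/S and for milk genes, 0.254 for G2/M, and 0.607 for interferon, DNA repair and ribosome biogenesis), and fry did not call interferon (adjusted p = 0.0561) or ribosome biogenesis (0.0797). Of 37 G1/S and DNA replication genes 26 were higher and 0 lower (median 1.09; 34 adjusted over the list alone), led by Mcm3 (1.84 ± 0.20), Cdt1 (1.90 ± 0.25) and Cdc45 (1.71 ± 0.25). Of 34 G2/M genes 23 were higher (median 1.32; 31 adjusted over the list alone), with Cdc20 (1.56 ± 0.23), Nuf2 (1.49 ± 0.22) and Ckap2l (1.64 ± 0.24). DNA repair genes were higher in 7 of 29 (median 0.74; 15 adjusted over the list alone), led by H2afx (1.36 ± 0.24), Timeless (1.18 ± 0.25) and Blm (1.34 ± 0.29), and ribosome biogenesis genes in 3 of 30 (median 0.52; 4 adjusted over the list alone), led by Nop2 (1.10 ± 0.20), Dkc1 (0.93 ± 0.24) and Bop1 (1.18 ± 0.31). The calls of Timeless (adjusted p = 0.0543 to 0.0571) and Blm (0.0548 to 0.0635) were lost without WT replicate 1, 2, 3 or 4, that of Dkc1 without these or SPON replicate 1 or 4 (0.059 to 0.102), and that of Bop1 without any 1 library other than SPON replicates 2 and 5 (0.0582 to 0.104). Interferon-stimulated genes were lower in 14 of 41 and higher in 1 (median -1.53; 27 and 2 adjusted over the list alone), with Ifi44 (-3.40 ± 0.67), Ifit1 (-2.97 ± 0.60) and Irf9 (-1.31 ± 0.27). Milk and alveolar genes were lower in 7 of 17 (median -1.72; 8 adjusted over the list alone), led by Lalba (-9.43 ± 0.62), which encodes alpha-lactalbumin, Wap (-7.31 ± 0.75) and Lao1, which had 1 count over the SPON libraries and was 7000-fold lower by summed counts (95% counting interval 1260 to 277000). Lao1 stood at 355 CPM in WT replicate 1 and at most 35.2 CPM in the other WT libraries. It was 1930-fold lower (347 to 76400) without that library and at least 1710-fold lower without SPON replicate 2, which held the 1 count. Ifit1 stood at -3.62 without SPON replicate 3 and Wap at -8.16 without SPON replicate 1.

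Bpifa2, a salivary secretory gene, had the largest log2 fold change of the named genes, 14.48 ± 3.71, and was highest in SPON replicate 5, with 32400 CPM against at most 387 CPM in the rest of the group. Without SPON replicates 3 and 5, a choice made after seeing the data, it was not called (adjusted p = 0.175), nor were Dcpp1 (6.98 ± 1.89, adjusted p = 0.238 without them), Bpifb5 (7.53 ± 2.08, 0.373) and Bsn (6.98 ± 1.53, 0.085). Alox12e (8.93 ± 1.47), Gpx2 (8.14 ± 1.31), Pdk4 (7.72 ± 1.14) and Bpifb1 (7.46 ± 1.24) were also among the 8 largest. Among the smallest, Adra2c and Klk10 had 0 counts in the SPON libraries and were at least 420-fold and 348-fold lower than in WT. Saa1 (-11.17 ± 1.12) and Saa2 (-8.92 ± 0.97) were lower as well, as were Hepacam2 and Slitrk4, with 1 and 2 SPON counts and 510-fold (91.2 to 20200) and 350-fold (96.6 to 2890) more in WT by summed counts. Klk10 stood at 53.7 CPM in WT replicate 3 and at most 9.27 CPM in the other WT libraries. Its bound was 99.3-fold without that library, and the bound of Adra2c was 255-fold without WT replicate 1. Without the library that held their SPON counts, Hepacam2 (SPON replicate 4) and Slitrk4 (SPON replicate 2) were at least 136-fold and 170-fold lower. Without SPON replicate 5 the log2 fold change was 8.48 for Bpifa2 and 4.73 for Dcpp1. Without WT replicate 2, Bpifa2 had 1 WT count and was 402000-fold higher in SPON by summed counts (72200 to 15900000). Without SPON replicate 3, Bpifb1 stood at 6.17, Gpx2 at 7.54, Bpifb5 at 6.87 and Bsn at 6.35, the last pair also without SPON replicate 5. Without SPON replicate 2, Pdk4 stood at 6.79 and Saa2 at -9.62, and Saa1, then at 0 SPON counts, was at least 2540-fold lower, while Alox12e stood at 7.44 without SPON replicate 4. Among WT libraries, Gpx2 (8.87) and Bsn (7.69) moved without replicate 2, Saa1 (-10.37) without replicate 3, Bpifb1 (8.14) and Bpifb5 (8.22) without replicate 4, and Pdk4 (9.45) without replicate 5. The calls of Bpifa2 (adjusted p = 0.0646 to 0.0955), Dcpp1 (0.0592 to 0.106) and Bpifb5 (0.0694 to 0.112) were lost without any 1 WT library, the last pair also without SPON replicate 3 or 5, and Bsn without WT replicate 1, 3 or 4 (0.0562 to 0.0565), and limma voom called none of Bpifa2, Alox12e, Gpx2, Bpifb1, Bpifb5, Dcpp1 and Bsn. Saa1 and Saa2, and members of the Bpif and Dcpp families, resemble each other in sequence, so reads may be divided between them.

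The count of 1303 fell to 550, 508, 545 and 506 without WT replicates 1, 2, 3 and 4, with 234, 237, 240 and 218 genes higher and 316, 271, 305 and 288 lower in SPON, so that most were lower. Without WT replicate 5, 495 were higher and 515 lower. DESeq2 called 2852 genes, 1488 higher and 1364 lower. Without SPON replicates 1 and 5, left out after the data were seen, 1204 genes passed, 804 of them among the 1303. Camera called 18 of 44 lists, 14 up and 4 down, and 12 of them without SPON replicates 1 and 5 (9 up and 3 down). The further called lists, by median log2 fold change, were CDK1 and its regulators (0.82), oxidative phosphorylation (0.31), EMT and claudin-low (1.10), macrophages (0.85), pericytes (1.07), fatty acid synthesis (-0.42), p53 targets (-0.38), cytokines (0.91), glycolysis (0.71), senescence secretory genes (1.18), hypoxia (0.56) and endothelium (0.59). None of the 18 held with an estimated correlation (adjusted p = 0.15 to 0.695), and fry called 6. Cytokines and senescence secretory genes were lost without SPON replicate 1 (adjusted p = 0.0697) or 4 (0.0515), endothelium without SPON replicate 3 or 5 or WT replicate 1 or 5 (0.0569 to 0.298), glycolysis without SPON replicate 1 or 2 or WT replicate 4 (0.0535 to 0.0697), hypoxia without SPON replicate 1 or 4 or WT replicate 4 (0.0886 to 0.204), and oxidative phosphorylation without SPON replicate 5 (0.0523).

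**Figure D3:**
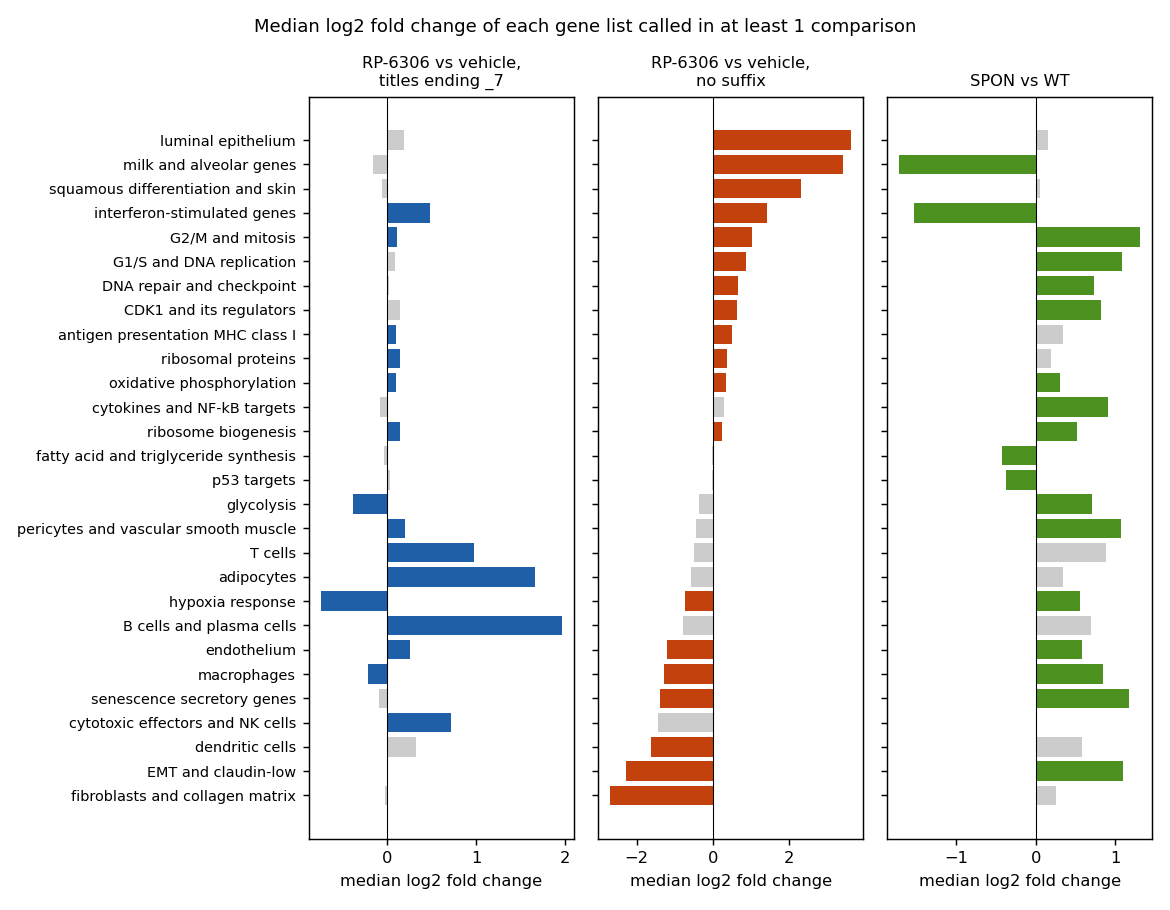
Median log2 fold change (horizontal axis) of each gene list called by camera in at least 1 of the 3 comparisons, with coloured bars where the list was called and grey bars where it was not; the scales differ between panels. Luminal epithelium has a median of 3.65 and fibroblast and collagen genes -2.70 in the set without the suffix.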

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

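The tests of chromosome windows, of the slope between sets, of stromal markers and of salivary genes were chosen after the results they concern had been seen, and the counts over other splits of the libraries were planned before they were run. Among 168 groups of values examined for a sample far from the others, 19 stood out here. The RP-6306 libraries without the suffix (n = 11) and the vehicle libraries titled _7 (n = 3) were outside the group sizes examined. No sample of these groups was checked in this way. A chance rate of about 1 in 20 cannot be assumed for them, because many of the genes were chosen for their large folds. For Ptprt, Lao1, Saa1, Hepacam2 and Slitrk4 the other libraries of the group had no counts, so any count would stand out. How many of the 19 chance alone would give is therefore not known. Groups without a sample named below were not shown to be free of one.

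In the set titled _7, Cd4 was high in RP-6306 replicate 2 (14.6 CPM, the next 6.15), and RP-6306 replicate 1 had the lowest mitochondrial share (1.33%, the next 1.55%). In the set without the suffix, vehicle replicate 1 stood above the other vehicle tumours for Epcam (239 CPM), Alox12e (2.94 CPM), Ptprt (0.0653 CPM) and Erbb2 (58.9 CPM), and vehicle replicate 4 for Ccne2 (14.1 CPM). In SPON, replicate 2 was high for Mki67 (939 CPM, the next 526), replicate 5 for Bpifa2 (32400 CPM) and Dcpp1 (11300 CPM), and values of near 0 stood out for Lao1 (0.0517 CPM), Saa1 (0.207 CPM) and Slitrk4 (0.103 CPM) in replicate 2 and Hepacam2 (0.0646 CPM) in replicate 4. In WT, Lao1 was high in replicate 1 (355 CPM, the next 35.2), Bpifa2 (1.40 CPM) and the mitochondrial share (7.75%) in replicate 2, Klk10 in replicate 3 (53.7 CPM) and Pdk4 in replicate 5 (1.34 CPM).

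The log2 fold changes of RP-6306 against vehicle differed between the sets at 6151 genes by the test of the difference. An effect of RP-6306 and a difference between tumours cannot be told apart for this count, as for the set without the suffix below. Redrawing treatment labels within the sets 100 times, the real labels included, gave as many genes 1 time, with at most 1 gene in the others. This argues against chance labels in both sets at once for this count, if the libraries are independent, which the labels do not state. Redrawing removes the difference between treated and vehicle tumours within each set, so it cannot test whether the sets share the same effect. Among named genes, the differences of log2 fold change were 1.65 for Pkmyt1, 0.63 for Wee1, 1.26 for Cdk1, 1.39 for Ccnb1, 1.5 for Mki67 and -1.41 for Ccne1. Upward they were 11.83 for Krt15, 10.67 for Alox15, 9.75 for Nlrp9b, 9.44 for Alox12e, 8.83 for Fstl4, 8.81 for Glt1d1, 8.45 for Ybx2, 8.07 for Rps6ka6 and 4.66 for Epcam. Downward they were -12.83 for Otop1, -11.01 for Bmp5, -10.04 for Acta1, -9.57 for Gdf10, -9.48 for Lypd6, -9.24 for Acan, -9.24 for Kcna4, -8.64 for Gzmf and -2.57 for Vim. These sizes, with and without 1 library, are fitted and depend on the prior count. Krt15, Alox15, Nlrp9b, Fstl4, Glt1d1 and Ybx2 had 0 counts in the RP-6306 libraries titled _7, and Otop1 and Bmp5 in the vehicle libraries titled _7, so they are no bounds for these genes. Against a floor of 3 counts over that group, the difference was at least 9.92 for Krt15, and at least 6.46 without vehicle replicate 1 of the set titled _7 and 10.75 without vehicle replicate 1 of the other set. No bound is given for Alox15, Ybx2 and Otop1, where it would rest on 1 library. None is given either for Nlrp9b, Fstl4, Glt1d1 and Bmp5, which had 2 or 3 counts in a further group, or for Alox12e, Lypd6 and Kcna4, with 3 counts in 1 group, and Gzmf and Rps6ka6 were left with 3 counts in 1 group without vehicle replicate 2 and RP-6306 replicate 4 of the set titled _7. The calls of Nlrp9b (6.65, adjusted p = 1) and Fstl4 (6.10, adjusted p = 1) were lost without vehicle replicate 3 and vehicle replicate 2 of the set titled _7. In that set the calls of Alox15 (8.25) and Alox12e (7.74) were also lost without vehicle replicate 1, those of Otop1 (-7.85) and Bmp5 (-9.17) without RP-6306 replicate 4, and that of Acta1 (-4.43) without RP-6306 replicate 3. In the same set Krt15 (8.54), Glt1d1 (7.95), Rps6ka6 (7.38) and Epcam (3.73) moved without vehicle replicate 1. There, too, Ybx2 (7.04), Gzmf (-10.12) and Acta1 (-15.80) moved without vehicle replicate 2, Alox12e (11.72) without RP-6306 replicate 1 and Rps6ka6 (8.75) without RP-6306 replicate 4. In the other set Krt15 (12.68), Alox15 (12.41), Nlrp9b (12.52), Alox12e (11.10), Glt1d1 (10.46), Ybx2 (9.87), Rps6ka6 (10.15) and Epcam (6.88) moved without vehicle replicate 1. Fstl4 (10.54) and Acta1 (-9.40) moved without vehicle replicate 2 of the other set, and Otop1 (-10.61) without vehicle replicate 4 of that set. Among its RP-6306 libraries, Acan (-10.06), Kcna4 (-10.15) and Gzmf (-10.48) moved without replicate 8, Bmp5 (-11.68) without replicate 7, Acta1 (-12.05) without replicate 9 and Otop1 (-13.89) without replicate 10.

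The 9531 genes of the set without the suffix were matched by 1 of 100 splits of its libraries, the real one, with at most 3367 genes in the others. This argues against a chance division of the libraries as the source of that count. Splits treat libraries as independent, which the labels do not state, so a chance difference between a few transplanted tumours stays open. As the whole cause of the 9531 genes, an effect of RP-6306 of the same size in both sets is argued against by a slope. The log2 fold changes of the set titled _7 had a slope of 0.016 on those of the other set, over 9017 genes. With 1 library left out it was -0.018 to 0.046. A shared effect beside a larger difference between tumours could give such a slope too, so it stays open. Treatment for different periods also stays open. More stroma of unchanged makeup around the same tumour cells is argued against as the whole cause. Fibroblast markers differed by 2.81 and endothelial markers by 1.27 between vehicle and RP-6306, a gap of 1.54 (two-sided exact permutation test over 1365 splits, p = 0.000733, the smallest they can give). A stroma richer in fibroblasts stays open. Counts of whole tumours do not show whether stromal or tumour cells carry these markers, so the test cannot tell a change of stroma from one of tumour cells. Tumours of different chromosome content may contribute, and by the bound of this test the values do not decide. Medians over 10 Mb windows spread 2.03 times as widely as over shuffled genes. This was above the ratio of 1.45 in the set titled _7, but by less than the 2 times set for this test. Their SD was 0.312, against at most 0.186 in 1000 shuffles. In the set titled _7 it was 0.0514, against at most 0.0418. Relative to all genes, chromosomes 9, 14 and 12 stood at -0.61, -0.49 and -0.45, and chromosome 13 at 0.32. In the set titled _7 these chromosomes stood at 0, 0.02, 0 and 0. Fold changes there were smaller in general (median absolute log2 fold change 0.147 against 0.596). Different chromosome content and an effect of RP-6306 therefore cannot be told apart here, since the labels give no tumour line for any sample. Between SPON and WT the ratio was 2.38, with chromosome 15 at 0.49 and chromosome 6 at 0.38. No bound was set for that comparison, so different chromosome content stays open there too.

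Salivary secretory transcripts were found in SPON replicates 3 and 5, where Bpifa2, BC037156 and Dcpp1 summed to 14300 and 53400 CPM. Tissue of an adult salivary gland, which could bring such transcripts, would also bring its other abundant genes. In replicate 5 the 11 other genes of a list written for this test summed to 0.909% of those 3, under its bound. Amy1 stood at 1.34 CPM, Prol1 at 3.72 CPM and Smr2 and Smr3a at 0. This argues against gland tissue as the whole source only if such tissue always makes the 11 in quantity. The 3 were chosen for their high values in these libraries, which lowers the percentage. Cst10 stood at 351 CPM (at most 0.221 CPM in WT) and Car6 at 117 CPM (12.1 to 486 CPM in WT), so cells that make these stay open. In replicate 3 they summed to 9.12%, between the bounds of this test, with Cst10 at 609 CPM and Prol1 at 500 CPM but Smr2 at 0.0681 CPM, so the question stays open there. The test was split by replicate, and a margin of 2 times added to its bound, after the 9.12% had been seen. SPON replicates 2 and 4 held 280 and 225 CPM of the 3 genes beside 1590 and 24.9 CPM of the 11 (567% and 11.1%, above the bound), so gland tissue stays open there. Replicate 1 was above the bound too (580%), with only 1.95 CPM of the 3 and 11.3 CPM of the 11. A high percentage is therefore no sign of gland tissue where the 3 are low. In replicate 2, Car6 at 876 CPM and Cst10 at 694 CPM made up most of the 11, and Smr2, Smr3a and Muc19 were at 0. No biological explanation was tested.

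The 1303 genes between SPON and WT were reached by 1 of 100 splits, the real one, with at most 1 gene in the others. This argues against a chance division of the libraries for that count, if they are independent, which the labels do not state. In the set titled _7 all 35 splits gave at least the real count of 0 genes, as any split must, so this tests nothing. The highest other split gave 1. The counts of called lists were not beyond chance: 26 of 35 splits gave as many as the 15 lists of the set titled _7 (at most 26), 11 of 100 as many as the 19 of the other set (at most 26), 13 of 100 as many as the 18 of SPON against WT (at most 22), and 34 of 100 as many as the 16 of the difference between sets (at most 23).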

How the results depend on the processing

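The comparisons without the 3 libraries nearest to the other group, without SPON replicates 1 and 5 or 3 and 5, and without mitochondrial genes were chosen after seeing the data. In these comparisons 8884 genes passed in the set without the suffix, of which 8561 were among the 9531, and 1204, 1179 and 1291 genes passed between SPON and WT, of which 804, 761 and 1283 were among the 1303. In the set titled _7, 6 genes passed without a filter on low counts and 60 with DESeq2, and 0 with any library left out. In the set without the suffix, 4744 genes passed at a fold of at least 2, where fewer can pass by construction, and 8480 to 9669 with 1 library left out. SPON against WT gave 2852 genes with DESeq2 and 5089 in 1 fit over the 32 libraries, and 506 to 1887 with 1 library left out (506 without WT replicate 4, 1887 without SPON replicate 2). With limma voom, 42.1% of its 1323 genes were higher in SPON, against 54% of the main count. The difference between sets gave 3922 genes at a fold of at least 2, 3575 in 1 fit over the 32 libraries and 5047 to 6345 with 1 library left out. The cause was not tested for the counts that moved with DESeq2, the missing filter or the common fit. Called lists fell to 0 in every comparison with an estimated correlation. The fry test called 0 lists in the set titled _7, 32 in the other set, 6 between SPON and WT and 21 for the difference. With 1 library left out, lists numbered 9 to 20 in the set titled _7 (9 without RP-6306 replicate 2), 18 to 20 in the other set, 16 to 20 between SPON and WT and 14 to 19 for the difference. G2/M and mitosis turned down in the set titled _7 without vehicle replicate 2 (adjusted p = 0.469, and 3.69e-08 to 0.689 over libraries left out), and ribosomal proteins turned down without RP-6306 replicate 2 (adjusted p = 0.972, and 5.74e-05 to 0.972); the cause was not tested. Of named genes called, 40 of 43 in the set without the suffix, 22 of 37 between SPON and WT and 14 of 24 for the difference kept their call under all alternatives. No paired analysis was possible because replicate numbers follow accession order and pair no samples. In simulated counts with 200 genes changed, 2-fold changes were recovered for 2.04% of changed genes in SPON against WT. In the real data 1303 genes passed, 1098 of them at a fold of at least 2. The adjusted threshold is less strict where more genes change. Real 2-fold differences may therefore have been missed, but the simulation does not give their share.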

Other observations

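The sample whose title and treatment field contradict each other belongs to no comparison. Its library had a mean correlation across genes of 0.95 with vehicle and 0.73 with RP-6306 libraries of the set without the suffix, and of 0.90 with both groups of the set titled _7. It held 31.6 CPM of Pkmyt1, 92.1 CPM of Cdk1, 62.9 CPM of Ccnb1, 11.2 CPM of Ccne1, 30.9 CPM of Cdkn1a, 141 CPM of Mki67, 1.37 CPM of Epcam and 5490 CPM of Vim.

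Trp53, which encodes the tumour suppressor p53 and was singled out after its values had been seen, stood at 3.58, 30.9, 37.4, 2.39 and 47.2 CPM in SPON replicates 1 to 5 and at 179 ± 50.6 CPM (SD, n = 5) in WT, a log2 fold change of -2.89 ± 0.71 (edgeR adjusted p = 0.031). The call was lost without any 1 of the WT libraries (adjusted p = 0.0551 to 0.0683). In the set without the suffix the mean of Trp53 was 33.1 CPM under RP-6306 and 26 CPM under vehicle. In the set titled _7 it was 56.4 and 48.1 CPM, so all 4 treated and vehicle groups lay under the WT mean. Of 32 fixed p53 target genes, 6 were lower in SPON and 0 higher over all genes, and 8 were lower and 3 higher when adjusted over the list alone (adjusted p = 0.607 with an estimated correlation).

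Across 15318 genes tested in both treated sets, log2 fold changes under RP-6306 had a Pearson r of 0.061 and a Spearman rho of 0.124, and 58.6% of the 9017 genes changed in the set without the suffix had the same sign in the set titled _7. Genes are not independent replicates.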
